A study of Mus musculus with 12 samples.

How the data were processed

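The series measured RNA from mouse dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, with or without a preceding sciatic nerve injury. Per the labels' protocols, lysate of fresh ganglia was immunoprecipitated with an antibody to CSDE1, an RNA-binding protein with cold-shock domains that acts in mRNA translation and stability. RNA from the immunoprecipitate (IP) was column-purified, and libraries were made with a Nanopore cDNA-PCR barcoding kit. The 12 samples fall into 4 groups of 3: input and IP of uninjured ganglia, and input and IP of injured ganglia, all wild type. The labels give no time after injury, number of animals or sequencing batch, and do not say whether replicates came from separate animals. P-values therefore measure the spread between these samples, which may be technical.

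The authors deposited a single table of read counts, whole numbers per Ensembl gene ID with no normalization. The submitters' processing notes name minimap2, a long-read aligner, Salmon, a transcript quantifier, and the mouse builds GRCm39 and mm39, without versions, settings or annotation. Salmon gives estimated counts, and whether such estimates were rounded to reach these deposited counts is not given in the sources used here. The table holds 19577 gene IDs, and the lowest sum of a gene over the 12 columns is 13. A symbol was found for 17438 IDs in a table pairing IDs with symbols, and 2139 IDs had none. No row was a total or an unassigned class. The other reference table gives genomic gene spans on an earlier build and no transcript lengths or GC content, so neither could be corrected for.

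Total counts per column were 3925351 to 3941973 in the uninjured inputs, 3829318 to 3925602 in the injured inputs, 989769 to 991163 in the uninjured IP columns and 1643033 to 1643433 in the injured IP columns. Columns of a group were compared by chi-square tests of their totals and of their counts per gene (Python 3.11.15, scipy 1.17.1). The 3 IP columns of each state were counted as 1 sample by summing their counts, for reasons given with the results. The fit thus held 8 libraries, 6 inputs and 1 IP sample per state, in place of the 12 of the written design.

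Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 4 groups (16556 genes), library sizes were scaled by TMM, and group means were fitted by quasi-likelihood (glmQLFit, glmQLFTest) with 4 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes were called at an adjusted p under 0.05 with no fold minimum. The lone IP sample of a state has no spread of its own and was assumed to vary like the inputs, which supply all 4 residual degrees of freedom, so the p-values of IP against input hold only under that assumption. The difference in IP enrichment between states, and injured against uninjured IP, rest on 1 IP sample per state. These have no replicate check and no p-values, and genes are listed by size: a change of at least 2-fold among genes with at least 100 counts over both IP samples, and for the enrichment difference also at least 100 over the inputs. Standard errors of these values, and the 95% exact Poisson intervals of IP levels, cover counting error only. Levels are TMM-scaled CPM (counts normalised to library size), with the SD of 3 libraries for inputs. Where all libraries of a group held 0 counts, a fold is a bound against 3 counts over the group, and against 1 to 3 counts it is a ratio with its exact Poisson counting interval.

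The tests, groups, alternatives and 31 gene lists were chosen before the data were examined. The lists hold injury-induced and regeneration-associated genes, markers of nociceptors, of mechanoreceptors and proprioceptors and of neurons in general, markers of satellite glia, myelinating and non-myelinating Schwann cells, macrophages, endothelial and mural cells, fibroblasts, erythroid cells and adipocytes with muscle, mRNAs named as CSDE1 targets elsewhere, RNA-binding partners of CSDE1, cytosolic and mitochondrial ribosomal proteins, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded mRNAs, translation factors, hnRNP and SR splicing factors, cholesterol synthesis, endoplasmic reticulum (ER) chaperones, collagens, tubulins with stathmins, proteasome subunits, voltage-gated ion channels, immediate early genes, interferon-stimulated genes, long non-coding RNAs, histones and heat shock proteins. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 31 lists. Where no test was possible, and for size, a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Further lists of very large and of small proteins were written after the data were seen, before their own values were.

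The genes named in the text follow a rule: Csde1; for each comparison the 6 largest rises and 6 largest falls among called genes with no overlap between the libraries compared, mean expression at or above the median, and a symbol that is not a clone, predicted gene or pseudogene; and the 2 called members of each list with the smallest p. In the untested comparisons the size rule stood in for the call. Genes outside the rule were chosen after their values were seen and are named as such.

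The steps were tested on simulated counts for all 16556 genes, with 200 genes changed. Counts of every library were drawn from the pooled input means, with the real library sizes and the fitted dispersions. The simulated IP samples thus had the composition and spread of the inputs. Their rates do not cover the measured IP composition or the spread between precipitates. For injured against uninjured input, 62.7%, 86.6% and 93.9% of genes changed 1.5-, 2- and 4-fold were called in the right direction, and 5.26% of calls were unchanged genes. For IP against input the values were 35.8%, 77.6% and 89.4% in uninjured ganglia, with 8.16% false calls, and 55.2%, 77.6% and 87.9% in injured ganglia, with 4.55%.

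Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library totals, no or a stricter low-count filter (at least 10 counts in at least 6 of the deposited columns), the compared groups alone, a fold threshold of 1.5 (glmTreat), the replicate number as a block, each column left out, and no mitochondrial, haemoglobin or ribosomal RNA genes. These last genes were found by symbol, so IDs without a symbol stayed in. For lists the alternatives were camera with an estimated correlation and fry. Added after the data were seen were the 12 columns as separate samples, as the design was first written, and limma on 1 log2 ratio per state, which tests the mean of both states.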

Results

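RNA was sequenced from dorsal root ganglia of wild-type mice, with or without a sciatic nerve injury, before (input) and after immunoprecipitation (IP) of the RNA-binding protein CSDE1. Each of the 4 groups had 3 samples. The inputs held 3829318 to 3941973 counts each, the uninjured IP columns 989769 to 991163 and the injured IP columns 1643033 to 1643433. The 3 IP columns of each state were counted as 1 sample, with 2970758 counts for uninjured and 4929527 for injured ganglia. Over high-count genes the uninjured IP columns differed by about the sampling noise, and otherwise the IP columns differed by slightly more than sampling noise. For these genes, with a mean of at least 1000 counts, the chi-square per degree of freedom between columns was 0.958 in uninjured IP (p = 0.634, 81 genes) and 1.13 in injured IP (p = 0.0264, 237 genes), against 4.75 and 12.1 in the inputs of the same states. Over all genes with a mean of at least 20 counts it was 1.17 and 1.18 in the IP columns and 1.66 and 2.52 in the inputs. This excess over sampling noise in the IP columns had p = 1.8e-40 (uninjured, 6448 genes) and p = 2.3e-54 (injured, 8694 genes) by the chi-square test. The 10 most abundant genes took 21.5% to 21.6% of counts in uninjured IP and 9.16% to 9.19% in injured IP, against 3.84% to 4.51% in the inputs. Gene IDs without a symbol took 8.57% to 8.68% of IP counts and 0.370% to 0.406% of input counts. Intervals and floors cover counting error only, as these PCR libraries were counted without molecular identifiers.

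The first comparison asked which RNAs were more abundant in the CSDE1 immunoprecipitate than in the input of uninjured ganglia. In this comparison and its injured counterpart the IP has 1 sample, so p-values and calls take its spread from the inputs, and the spread between precipitates was not measured. Most mRNAs of cytosolic ribosomal proteins, of the respiratory chain and of splicing factors were higher in the IP, and most of voltage-gated ion channels and nociceptor markers were lower. These 5 lists passed with a preset correlation and not with an estimated one (adjusted p = 0.239, 0.694, 0.555, 0.802 and 0.833). Bc1 (ENSMUSG00000115783), a short non-coding RNA of neurons made by RNA polymerase III, stood at 0.700 ± 0.411 CPM (SD, n = 3) in the input and at 105609 CPM (95% counting interval 105177 to 106041, 1 sample) in the IP, where it made up 7.74% of counts. Rpl38, a protein of the large ribosomal subunit, was at 62.0 ± 4.10 CPM in the input and 2754 CPM in the IP. Scn10a, the sodium channel Nav1.8 of nociceptors, was at 1195 ± 105 and 139 CPM. Csde1 (ENSMUSG00000068823) mRNA was at 385 ± 45.1 CPM in the input and 501 CPM (472 to 532) in the IP, a log2 ratio of 0.38 (SE 0.12, adjusted p = 0.0112) that turned to -0.20 (adjusted p = 0.160) when scaled by library totals and lost its call with limma-voom (0.39, adjusted p = 0.147). The other largest rises among abundant genes under the naming rule were Lrrc17 (log2 14.92), the kinase anchor Akap5 (13.53) and the riboflavin transporter Slc52a2 (9.25, SE 0.10). The glutathione peroxidase Gpx1 (8.33) and the ATP synthase subunit Atp5k (7.07) followed. Ppp1cc, Raf1 and Pla2g6, which encode a phosphatase, a kinase and a phospholipase, had no IP count and were at least 40.2-, 37.4- and 24.0-fold lower. The receptor-like phosphatase Ptprn2, the nicotinic receptor subunit Chrna7 and the sodium-proton exchanger Slc9a7 had 1 IP count each. Their ratios were 207-fold (counting interval 37.2 to 8190), 179-fold (32.2 to 7083) and 119-fold (21.3 to 4695) lower.

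Of 84 cytosolic ribosomal protein mRNAs in uninjured ganglia, 72 were higher in the IP and 7 lower, with a median log2 of 1.83 (camera adjusted p = 1.53e-08, adjusted p = 0.239 with an estimated correlation). Rpl23a stood at log2 8.30 and Rpl38 at 5.47 (SE 0.083). Among 78 mitochondrial ribosomal proteins 51 were higher and 8 lower (53 and 8 adjusted over the list alone), with Mrps21 at 8.11 and Mrps26 at 3.93 (median 0.96, adjusted p = 0.0027, 0.239 with an estimated correlation). Of 80 nuclear-encoded oxidative phosphorylation mRNAs, 63 were higher and 11 lower, with Atp5mpl at 6.99 (median 2.02, adjusted p = 2.607e-06, 0.694 with an estimated correlation). Of the 13 mRNAs made inside mitochondria, 11 were higher and 2 lower, with mt-Co3 at 12.06 (median 3.65, adjusted p = 0.0087, 0.694 with an estimated correlation). Another, mt-Atp6, had 3 input counts, or 0.233 CPM, and stood at 2444 CPM in the IP. In the input mt-Co3 stood at 0.544 CPM, against 1895 CPM for mt-Co1, and mt-Atp8 and mt-Nd4l had no count. Whether such ratios come from a difference in library preparation between input and IP was not tested. Of 31 hnRNP and SR splicing factors, 25 were higher and 2 lower, among them Hnrnpf at 2.61 and Hnrnpa0 at 1.76 (median 0.90, adjusted p = 0.0027, 0.555 with an estimated correlation). RNA-binding partners and cold-shock relatives of CSDE1 were higher for 11 of 13 and lower for none, with the poly(A)-binding protein Pabpc1 at 3.16 (SE 0.088) and the cold-shock protein Ybx1 at 2.69 (median 0.61, adjusted p = 0.0408, 0.506 with an estimated correlation).

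Lower in the uninjured IP were 45 of 68 voltage-gated ion channel mRNAs, with 6 higher (46 and 6 adjusted over the list alone), among them the potassium channel Kcnq2 at log2 -2.74. The channel median was -1.32, or -1.22 with genes at 0 set to their bound (adjusted p = 5.102e-06, 0.802 with an estimated correlation). Of 29 nociceptor and thermoreceptor markers 19 were lower and 5 higher, with the ATP receptor P2rx3 at -3.85 and Scn10a at -3.11 (median -1.26, adjusted p = 0.0046, 0.833 with an estimated correlation). Cholesterol synthesis mRNAs were lower for 15 of 22 and higher for 5, with the reductase Dhcr24 at -1.70 and the regulator Srebf2 at 1.80 (median -0.60, adjusted p = 0.0367, 0.927 with an estimated correlation). Erythroid genes were higher for 4 of 5 (median 5.20, adjusted p = 0.0417, 0.506 with an estimated correlation). As the globin copies share reads, they were summed, which gave 61.0-fold higher alpha globin and 126-fold higher beta globin in the IP.

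The remaining lists did not pass in uninjured ganglia. Higher and lower members in the IP numbered 14 and 5 of 38 regeneration-associated genes, 6 and 13 of 21 mechanoreceptor markers and 10 and 11 of 24 pan-neuronal genes. Among glia they numbered 7 and 6 of 16 satellite glia markers, 10 and 4 of 18 myelinating Schwann cell markers (10 and 5 adjusted over the list alone), and 5 and 4 of 12 non-myelinating Schwann cell markers. Gap43, a growth cone protein, stood at log2 2.22, the neurofilament Nefm at 1.85, Elavl3 at 2.31, the actin regulator Avil at -2.88 and the myelin protein Mbp at 1.51. The numbers were 5 and 3 of 23 macrophage markers (4 and 1 adjusted over the list alone), 2 and 5 of 17 endothelial and mural markers, 7 and 5 of 17 fibroblast markers, and 4 and 0 of 7 adipocyte and muscle genes. They were 4 and 1 of 8 mRNAs named as CSDE1 targets in other systems (adjusted p = 0.509, 0.00081 with fry), 29 and 21 of 65 translation factors, 7 and 9 of 21 ER chaperones and 4 and 11 of 34 collagens (3 and 11 adjusted over the list alone). Of cytoskeletal and proteasome genes they were 4 and 7 of 18 tubulins and stathmins, 16 and 9 of 37 proteasome subunits. They were 2 and 0 of 12 immediate early genes (none adjusted over the list alone), and 3 and 5 of 16 interferon-stimulated genes (3 and 4 adjusted over the list alone). They were 7 and 0 of 9 long non-coding RNAs, 13 and 11 of 46 histones (12 and 11 adjusted over the list alone), and 27 and 22 of 73 heat shock proteins. The initiation factor Eif1 was at 5.37, the ER chaperone Hspa5 at -1.88 and the imprinted non-coding RNA Meg3 at 2.66. The histone median was -1.33 as fitted and 0.40 with genes at 0 set to their bound, and the regeneration median was 0.32 and 0.85. For satellite glia and fibroblasts the mean (-0.08 and -0.01) differed in sign from the median (0.06 and 0.37). For macrophages, translation factors and heat shock proteins the median and mean were above 0 and the test pointed down. For pan-neuronal genes the mean was 0.05 while the median and the test pointed down. The medians of endothelial markers (-0.12), tubulins (-0.06) and pan-neuronal genes (-0.00) turned positive with RLE scaling.

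If the lone IP sample varied like the inputs, which could not be checked, then over all 16556 genes tested in uninjured ganglia 6166 were higher and 4947 lower in the IP, of which 4932 and 3341 by at least 2-fold. Scaling by library totals moved the median of all genes by -0.58 and RLE by 0.12, and with library totals 4621 genes were higher and 7391 lower, 38.5% higher in place of 55.5%. Library totals also turned the medians of regeneration genes (-0.19), satellite glia, both Schwann cell lists, macrophages, fibroblasts, CSDE1 targets (-0.12), translation factors, proteasome subunits, immediate early genes and heat shock proteins below 0. Reads of overlapping genes and of near-identical copies, histones and ribosomal protein pseudogenes included, could not be told apart.

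The same comparison in injured ganglia gave high values for ribosomal protein, mitochondrial and proteasome mRNAs in the IP and low values for ion channel, nociceptor and collagen mRNAs. With an estimated correlation no list passed (lowest adjusted p = 0.0874). Eif1 rose from 60.2 CPM in the input to 4097 CPM in the IP (log2 6.09), and Rpl38 from 74.6 to 3548 CPM (5.57). Bc1 stood at 26939 CPM in the IP (log2 14.78) and made up 2.00% of counts. The other largest rises among abundant genes that met the naming rule were Lrrc17 at 12.86, Akap5 at 11.80, Gpx1 at 7.78, Atp5k at 7.31 and the NAD synthesis enzyme Nmnat1 at 7.31. Csde1 mRNA was at 396 ± 48.0 CPM (SD, n = 3) in the input and 534 CPM (511 to 558) in the IP, a log2 ratio of 0.43 (SE 0.12, adjusted p = 0.0028) that turned to -0.15 (adjusted p = 0.250) with library totals and lost its call with limma-voom (0.44, adjusted p = 0.0783). Ppp1cc again had no IP count and was at least 61.6-fold lower. On 2 or 3 IP counts, the histone gene Hist1h4d was 89.7-fold lower (counting interval 24.8 to 740.5), the cold receptor Trpm8 66.9-fold (18.5 to 552), Slc9a7 59.5-fold (20.4 to 288.5) and Chrna7 58.7-fold (16.2 to 484). The angiogenesis inhibitor Vash1 fell by 6.05 on the log2 scale.

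Of the 84 cytosolic ribosomal protein mRNAs in injured ganglia 77 were higher and 4 lower in the IP, with Rpl23a at log2 8.18 (median 2.62, adjusted p = 4.776e-12, 0.0874 with an estimated correlation). Mitochondrial ribosomal proteins were higher for 63 of 78 and lower for 5, with Mrps26 at 4.59 (median 1.53, adjusted p = 1.093e-05, 0.0874 with an estimated correlation). Oxidative phosphorylation mRNAs were higher for 66 of 80 and lower for 8 (median 2.66, adjusted p = 2.105e-08). mRNAs made inside mitochondria were higher for 12 of 13 and lower for 1, with mt-Co2 at 12.33 (median 3.60, adjusted p = 0.0050). Proteasome subunits were higher for 26 of 37 and lower for 3, with Psma7 at 2.76 and Psmc5 at 2.10 (median 0.65, adjusted p = 0.0172). Ion channel mRNAs were lower for 49 of 68 and higher for 6 (49 and 7 adjusted over the list alone), with Cacna1b at -2.74 (median -1.03, adjusted p = 3.784e-06). Nociceptor markers were lower for 18 of 29 and higher for 4, with P2rx3 at -4.16 and Scn10a at -3.27 (median -1.0, adjusted p = 0.0044). Collagens were lower for 15 of 34 and higher for 5, with Col4a2 at -2.02 (median -0.71, adjusted p = 0.0224). None of these last 6 lists passed with an estimated correlation. In the injured input mt-Co2 stood at 0.463 CPM. Erythroid genes were higher for 4 of 5 (median 5.31, adjusted p = 0.0466, 0.676 with an estimated correlation), with summed alpha globin 61.1-fold and beta globin 156-fold higher.

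Among lists that did not pass in injured ganglia, 24 of 38 regeneration-associated genes were higher and 10 lower (25 and 10 adjusted over the list alone), with the neuropeptide Gal at log2 3.26, the transcription factor Klf6 at 3.08 and Gap43 at 2.93. The regeneration median was 0.58 and -0.01 with library totals. Splicing factors were higher for 17 of 31 and lower for 3 (adjusted p = 0.15), CSDE1 partners for 7 and 1 of 13 (adjusted p = 0.235). mRNAs named as CSDE1 targets were higher and lower for 5 and 1 of 8 (adjusted p = 0.457, 0.00084 with fry), and cholesterol genes for 5 and 12 of 22 (adjusted p = 0.167). Pabpc1 was at 2.67, Hnrnpf at 1.88, Srebf2 at 2.72 and the glutamine synthetase Glul, a satellite glia marker, at -1.88. Library totals turned the medians of splicing factors (-0.23), CSDE1 partners (-0.22), CSDE1 targets (-0.20), pan-neuronal genes, satellite glia, myelinating Schwann cells, macrophages, translation factors and heat shock proteins below 0. For pan-neuronal genes, satellite glia and macrophages the median and mean were above 0 and the test pointed down. Under the same unchecked assumption on the lone IP sample, 6636 genes were higher and 5545 lower in all, 5296 and 3621 of them by at least 2-fold. With library totals 5134 were higher and 7998 lower, 39.1% higher in place of 54.5%, and the median of all genes moved by -0.58, against 0.13 with RLE.

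Lists by protein size, written after the data were seen, also parted in both states. The 57 genes of small proteins outside the ribosome, respiratory chain and proteasome had a median log2 of 2.17 in uninjured and 2.82 in injured ganglia, above all 10000 matched random lists. The 47 genes of very large proteins had medians of -1.49 and -1.60, below all of them.

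**Figure D1:**
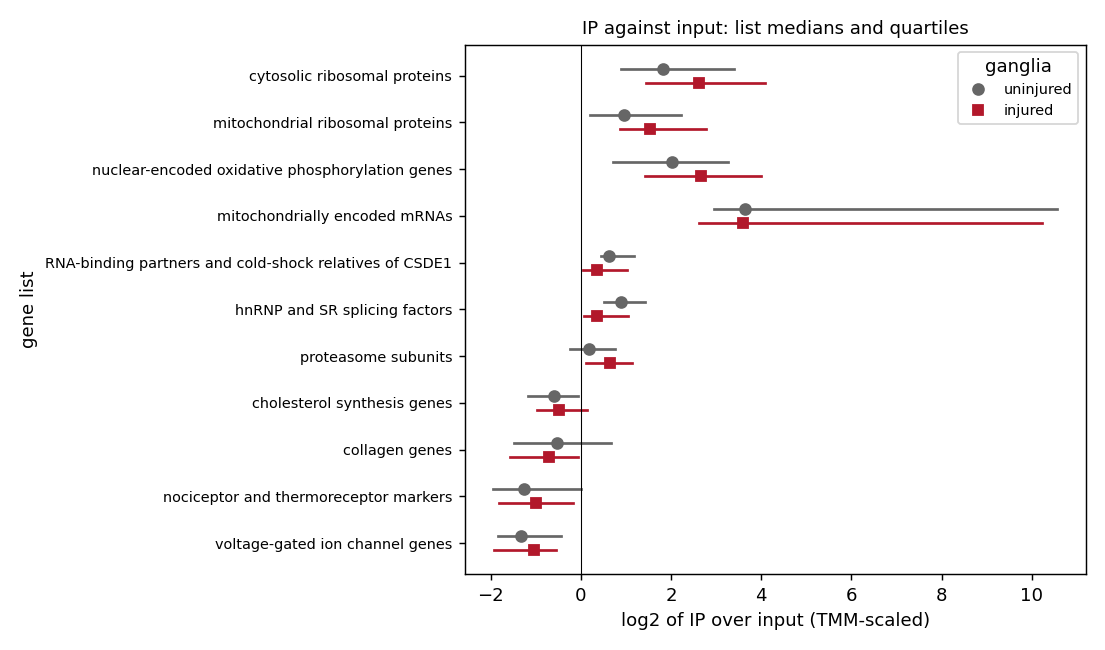
Median log2 ratio of IP over input for 11 gene lists in uninjured (circles) and injured (squares) ganglia, with lines from the lower to the upper quartile of the list's genes. Cytosolic ribosomal proteins lie at 1.83 and 2.62 and voltage-gated ion channels at -1.32 and -1.03, while the injured splicing factor median of 0.35 and CSDE1 partner median of 0.36, and the uninjured proteasome median of 0.17, turn negative with library totals.

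The next comparison asked whether enrichment in the IP differed between injured and uninjured ganglia. Ribosomal protein and nuclear-encoded respiratory chain mRNAs were more enriched after injury, and splicing factor mRNAs less, in comparisons of 1 IP sample per state that had no replicate check. Ubb, which encodes polyubiquitin, went from 95.5 CPM (83.0 to 109) in the uninjured to 1550 CPM in the injured IP while its input stood at 859 ± 36.2 and 973 ± 38.7 CPM (SD, n = 3). The difference in enrichment was log2 3.84 (counting SE 0.10). Map3k12, the dual leucine zipper kinase of axon injury signalling, went from 200 to 27.0 CPM in the IP, a difference of -2.38. The difference for Csde1 was 0.05.

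Other large gains in enrichment were Rpl29 at log2 4.28 (counting SE 0.60, on 6 uninjured IP counts), the ciliary gene Tctn1 at 3.55, Mettl7a3 at 3.44 (on 5 uninjured IP counts), Hip1 at 3.12 and the succinyl-CoA ligase Suclg1 at 3.09. Without replicate 3 of the uninjured IP the count of Rpl29 was 0 and its fitted difference 10.7, which depends on the prior count. Losses were Slc52a2 at -2.71, Elp6 at -2.16, the xanthine dehydrogenase Xdh at -2.05, Nme7 at -1.97 and the phosphatase Dusp1 at -1.95. Cytosolic ribosomal proteins with enough counts had a median difference of 0.77 (74 genes, 22 up by at least 2-fold and 0 down). It was 0.57 for mitochondrial ribosomal proteins (64 genes) and 0.62 for oxidative phosphorylation genes (78 genes), each of the 3 above all 10000 matched random lists. The mRNAs made inside mitochondria did not share this rise, with a median of -0.18 (7 genes, 2 above and 5 below 0, 21.49th percentile). Rpl21 stood at 1.87, Rps8 at 1.63, Mrpl20 at 1.44, Cox7b at 1.15 and Atp5g1 at 1.11. Proteasome subunits had a median of 0.37 (99.94th percentile), interferon-stimulated genes of 0.90 (5 genes, 99.13th), translation factors of 0.23 (99.48th) and heat shock proteins of 0.21 (98.9th). The 51 small-protein genes had a median of 0.59 (above all random lists) and the 37 very large ones of -0.03 (41.68th percentile).

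At the low end of the difference in enrichment were splicing factors (29 genes, median -0.40, 0.01st percentile), fibroblast markers (10 genes, -0.50, 0.27th), myelinating Schwann cell markers (14 genes, -0.41, 0.47th), long non-coding RNAs (9 genes, -0.48, 0.855th) and collagens (12 genes, -0.40, 1.17th). The regeneration-associated median was 0.22 (34 genes, 92.82nd percentile), or 0.04 with genes at 0 set to their bound, with Gal at 1.75 and Gadd45a at -1.19. Nociceptor markers had a median of 0.00 (52.39th percentile), ion channels of -0.04 (33.97th) and mRNAs named as CSDE1 targets of 0.06 (6 genes, 61.77th). Satellite glia markers had a median of 0.05 (62.14th percentile) with the secreted protease inhibitor Cst3 at 1.47, mechanoreceptor markers of 0.10 with Ntrk3 at 1.14 and Spp1 at -1.35, and pan-neuronal genes of -0.11 with Avil at 1.24.

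Of 7465 genes with at least 100 counts in both the inputs and the IP samples, 439 were more and 182 less enriched by at least 2-fold after injury. The IP minimum sums both IP samples, of which the injured one held more counts, so genes higher in the injured IP passed it more easily. Across all 16556 genes tested, enrichment in both states had a Pearson r of 0.919 and a Spearman rho of 0.890, and across the 7465 genes 0.913 and 0.902. Genes are not independent replicates. A difference between IP and input libraries shared by both states would raise these correlations, and also the overlap that follows. Of genes called and at least 2-fold higher in the IP, 4307 were shared between states, against 1578 for independent lists, and of those lower 2527, against 731. The share of the 10 most abundant genes also differed between the IP samples, and Lrrc17 took 4.65% of uninjured and 0.872% of injured IP counts.

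**Figure D2:**
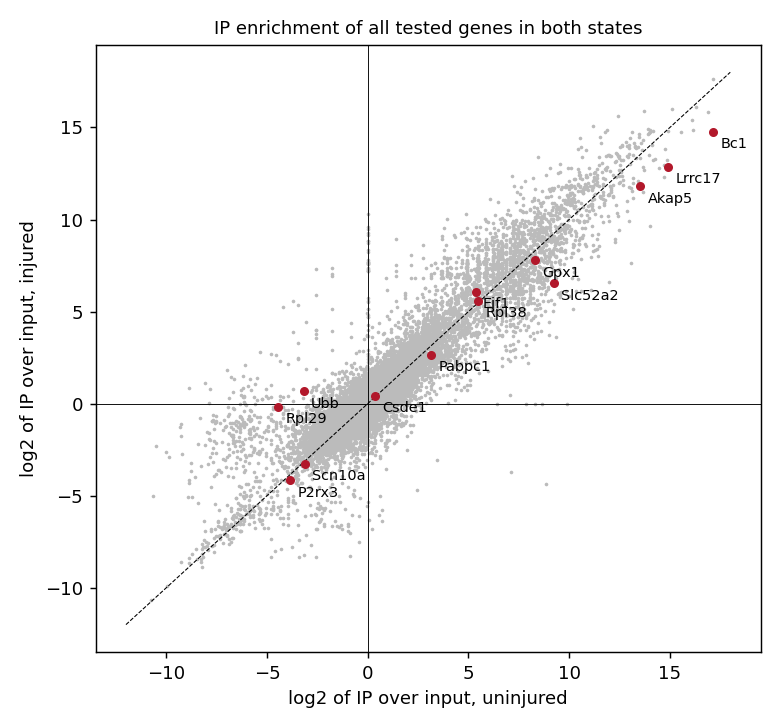
Log2 ratio of IP over input in uninjured (x axis) and injured (y axis) ganglia, 1 grey point per tested gene, with selected genes in red and a dashed line of equal values. Across genes r was 0.919, Ubb and Rpl29 lie above the line and Bc1 and Slc52a2 below it, and points of genes without counts in a group depend on the prior count.

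For injured against uninjured input, which asked what nerve injury changed in the ganglia, most injury-induced genes rose and most mRNAs of sensory neuron subtypes and ion channels fell. These lists passed with a preset correlation and not with an estimated one (adjusted p = 0.198 for injury-induced genes and 0.305 for the others). Atf3 (ENSMUSG00000026628), a stress transcription factor, rose from 7.99 ± 0.625 to 598 ± 68.7 CPM (SD, n = 3 and 3), log2 6.22 (SE 0.12, adjusted p = 9.037e-18). The neuropeptide galanin (Gal) rose from 12.4 ± 1.29 to 347 ± 45.0 CPM (log2 4.80), and the transcription factor Sox11 from 14.6 ± 3.92 to 225 ± 25.1 CPM (3.94). Most markers of macrophages and fibroblasts and most adipocyte and muscle transcripts also rose, in lists with an adjusted p = 0.305 each with an estimated correlation. Csf1r, the receptor for a macrophage growth factor, went from 16.1 ± 2.37 to 51.5 ± 8.0 CPM, and Car3, a carbonic anhydrase of muscle and fat, from 2.17 ± 0.568 to 52.8 ± 6.84 CPM.

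Lmo7 (log2 4.03), the metalloprotease Adam8 (3.9) and the stathmin Stmn4 (3.79) were among the other largest rises. The largest falls were the potassium channel subunit Kcnmb1, from 33.6 ± 4.65 to 8.96 ± 1.19 CPM (log2 -1.90, SE 0.15), and Chrna6 (-1.61). The serotonin receptor Htr3a fell from 159 ± 27.3 to 53.1 ± 7.88 CPM (-1.58) and the nociceptor receptor Mrgprd from 205 ± 8.09 to 76.2 ± 11.9 CPM (-1.43). Ccdc74a (-1.39) and Dpp10 (-1.38) came next. Csde1 did not pass, with log2 0.04 (adjusted p = 0.819).

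Of 38 regeneration-associated genes 37 rose and 1 fell, with Gap43 at log2 2.02 (median 3.11, adjusted p = 2.723e-28, 0.198 with an estimated correlation). Tubulins and stathmins rose for 10 of 18 and fell for 3, with Tubb6 at 3.10 (adjusted p = 0.0036, 0.342 with an estimated correlation). Of 29 nociceptor markers 24 fell and 3 rose, with the glutamate receptor Grik1 at -1.06 (median -0.83, adjusted p = 7.968e-09). Of 21 mechanoreceptor and proprioceptor markers 20 fell and 1 rose, with the sodium channel Scn1a at -0.97 and the neurofilament Nefh at -0.61 (median -0.61, adjusted p = 2.092e-08). Of 68 voltage-gated ion channels 44 fell and 3 rose (46 and 4 adjusted over the list alone), with Kcnh7 at -1.37 and Cacna2d1, the gabapentin-binding calcium channel subunit, at 1.93 (median -0.56, adjusted p = 7.779e-09). With an estimated correlation these 3 lists had an adjusted p = 0.305. Pan-neuronal genes rose for 5 and fell for 12 of 24 (6 and 13 adjusted over the list alone, list adjusted p = 0.0962), with Tmem233 at -1.16 and Stmn2 at 0.76.

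Of 23 macrophage markers 16 rose and none fell (17 adjusted over the list alone), with the mannose receptor Mrc1 at log2 2.32 (median 1.66, adjusted p = 1.886e-06). Of 17 fibroblast markers 14 rose, with the lipid carrier Apod at 1.27 and the proteoglycan Lum at 1.12 (median 0.70, adjusted p = 2.548e-05). Of 34 collagens 18 rose and 1 fell (19 and 1 adjusted over the list alone), with Col5a3 at 0.87 (adjusted p = 0.00042), and of 7 adipocyte and muscle genes 6 rose, with the muscle actin Acta1 at 2.84 (list adjusted p = 0.0044). Each of these 4 lists had an adjusted p = 0.305 with an estimated correlation, and Acta1 lost its call with limma-voom (2.68, adjusted p = 0.0986). Myelinating Schwann cell markers rose for 5 of 18, with the myelin protein Plp1 at 0.37 (list adjusted p = 0.0324, 0.510 with an estimated correlation), a gene that lost its call with limma-voom (0.36, adjusted p = 0.0541). Endothelial and mural markers rose for 7 and fell for 1 of 17 (adjusted p = 0.0544), non-myelinating Schwann cell markers for 4 and 3 of 12, and satellite glia markers for 2 and 2 of 16, with Glul at 0.93, the proteoglycan Bcan at -0.74, a list median of 0.01 and a mean of -0.02. None of 5 erythroid genes passed.

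Of 84 cytosolic ribosomal proteins 39 rose and 1 fell (49 and 1 adjusted over the list alone), with Rps26 at log2 0.58 and Rps3 at 0.44 (median 0.22, adjusted p = 8.564e-10, 0.198 with an estimated correlation). Translation factors rose for 23 and fell for 5 of 65, with Eef1b2 at 0.94 (adjusted p = 0.0166). ER chaperones rose for 8 and fell for 0 of 21 (9 and 1 adjusted over the list alone), with Chac1 at 2.23 and Atf4 at 0.83 (adjusted p = 0.0095), and splicing factors for 11 and 0 of 31 (adjusted p = 0.0058). These 3 lists each had an adjusted p = 0.305 with an estimated correlation. CSDE1 partners rose for 6 of 13 (7 rose and 1 fell adjusted over the list alone), with the cold-shock protein Carhsp1 at 1.11 (adjusted p = 0.0064), and histones for 13 of 46 with 1 lower (adjusted p = 0.0108), each with an adjusted p = 0.266 with an estimated correlation. Proteasome subunits rose for 10 and fell for 1 of 37 (adjusted p = 0.0010, 0.344 with an estimated correlation), and immediate early genes rose for 6 of 12, with Fosl2 at 1.82 (adjusted p = 0.0030, 0.363 with an estimated correlation). Oxidative phosphorylation genes fell for 18 of 80 and rose for none (17 adjusted over the list alone), with Ndufv3 at -0.51 (median -0.10, adjusted p = 0.0108, 0.510 with an estimated correlation). Lists that did not pass were mRNAs named as CSDE1 targets (5 higher and 1 lower of 8, Pabpc1 at 0.57), mitochondrial ribosomal proteins (1 and 4 of 78, or 1 and 2 adjusted over the list alone), and mRNAs made inside mitochondria (0 of 13). Neither did cholesterol synthesis (5 and 6 of 22, Hsd17b7 at 1.48), interferon-stimulated genes (2 and 0 of 16), long non-coding RNAs (5 and 0 of 9, adjusted p = 0.0512) and heat shock proteins (12 and 6 of 73, Hspb1 at 1.30).

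Over the 16556 genes 2336 rose and 2353 fell after injury in the input, 723 and 327 of them by at least 2-fold. DESeq2 called 1164 and 1270 and a fold threshold of 1.5 called 565 and 288. Beyond sampling noise, the inputs of a state varied by a median of 2.29% (uninjured) and 4.61% (injured) over high-count genes. The labels do not say whether these inputs are separate animals, so the calls may rest on technical spread alone. The 57 small-protein genes had a median log2 of 0.06 (86.34th percentile) and the 47 very large ones of -0.05 (31.4th).

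**Figure D3:**
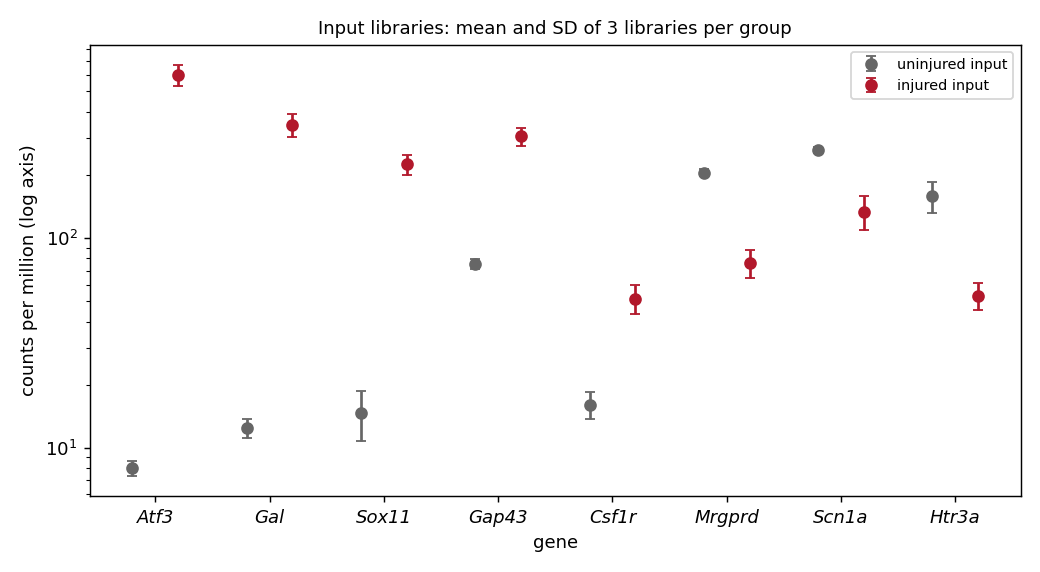
Mean level of 8 genes in uninjured (grey) and injured (red) input libraries, in counts normalised to library size on a log axis, with bars for the SD of 3 libraries. Atf3 goes from 7.99 to 598 and Mrgprd from 205 to 76.2.

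In the IP, injured against uninjured compared the RNA recovered with CSDE1, in 1 sample per state with no replicate check. Injury-induced genes again had the highest values. Gal went from 35.4 to 3325 CPM (log2 6.55, counting SE 0.16), Atf3 from 6.89 to 380 CPM (5.78, counting SE 0.37) and Gap43 from 351 to 2334 CPM (2.73). The 34 regeneration-associated genes with at least 100 IP counts had a median of 3.17, above all 10000 matched random lists, and 30 of them were higher by at least 2-fold. Csde1 stood at 0.09.

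Other high values were Mettl7a3 (log2 4.83), Lmo7 (4.63), Rpl29 (4.50, or 10.9 as fitted without replicate 3 of the uninjured IP, where its count was 0) and the adhesion protein Flrt3 (4.47). The lowest were Map3k12 (-2.89), Slc52a2 (-2.75), Lrrc17 (-2.44), Akap5 (-2.23), Tmem35a (-2.23) and the synaptic vesicle protein Synpr (-2.22). Without replicate 1 of the uninjured IP, Map3k12 stood at -2.49 and Slc52a2 at -2.71. Cytosolic ribosomal proteins had a median of 1.03 (82 genes, 43 at least 2-fold higher and 0 lower), with Rpl35 at 1.81. Medians were 0.53 for 80 oxidative phosphorylation genes with Cox7b at 1.27, 0.51 for 35 proteasome subunits with Psma7 at 1.31, 0.51 for 70 mitochondrial ribosomal proteins (99.98th percentile) and 0.36 for 58 translation factors with Eef1b2 at 1.67 (99.89th). The first 3 of these 5 lists, and the small-protein genes with 0.60, lay above all random lists, while very large proteins stood at -0.06 (44.17th percentile). Nociceptor markers (17 genes, median -0.75, with Tac1, the substance P precursor, at -1.46) and ion channels (40 genes, -0.61, with Kcnab2 at -1.11 and Cacna2d1 at 2.38) lay below all random lists, and mechanoreceptor markers at -0.70 (0.01st percentile). Macrophage markers had a median of 1.23 (10 genes, 99.97th percentile) with C1qa at 1.71, myelinating Schwann cell markers of -0.42 (0.99th), splicing factors of -0.26 (2.74th) and collagens of -0.01 (49.83rd, mean 0.11), a median that turned positive with library totals or RLE.

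Of 8536 genes with at least 100 IP counts, 1107 were at least 2-fold higher and 438 lower after injury. That minimum sums both IP samples, of which the injured one held more counts, so genes higher after injury passed it more easily. Across 7465 genes the injury change in input and IP had a Pearson r of 0.645, a Spearman rho of 0.509 and a slope of 0.958. Of 216 genes called at least 2-fold higher in the input among these, 212 (98.1%) were above 0 in the IP, against 51.9% of all genes, and 162 were at least 2-fold higher. Of 86 at least 2-fold lower in the input, 84 (97.7%) were below 0, against 48.1%, and 54 at least 2-fold lower.

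**Figure D4:**
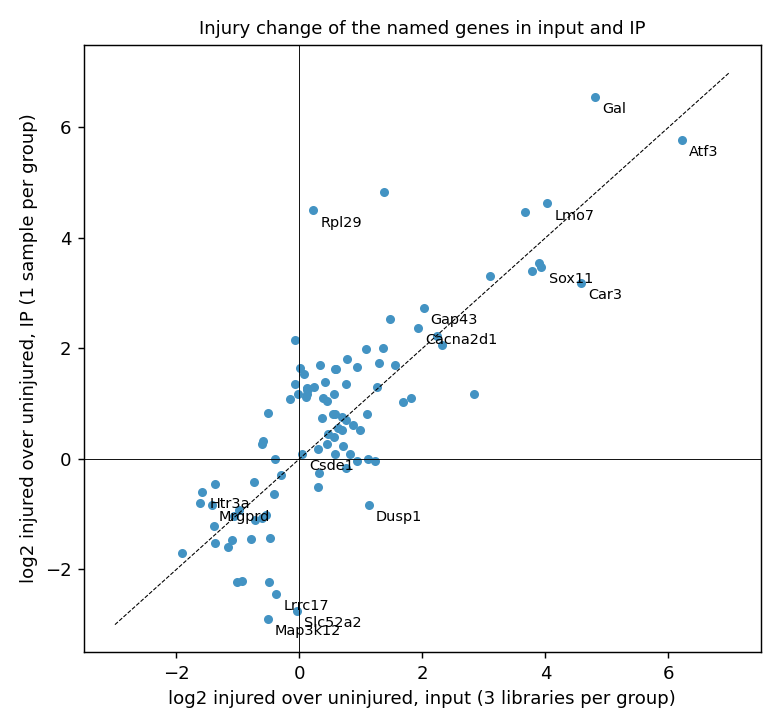
Log2 of injured over uninjured in input (x axis, 3 libraries per group) and IP (y axis, 1 sample per group) for the 101 named genes of both comparisons, with a dashed line of equal values. Gal (4.80 and 6.55) and Atf3 (6.22 and 5.78) lie at the high end, while Rpl29, Map3k12 and Slc52a2 moved in the IP by 4.50, -2.89 and -2.75.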

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

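The tests of protein size, recovery, input change, scaling and shared reads given here, and the split of the input libraries, were chosen after the results were seen.

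For 12 of 44 genes named in the comparison of enrichment, the IP lay above all inputs in one state and below all inputs in the other. These differences were not tested, as each state has 1 IP sample. Apart from Csde1, the genes were named for the size of this same difference, which favours opposite signs. The share among all genes was not counted. Ubb differed by log2 3.84 between injured and uninjured ganglia, from -3.17 to 0.67. Hip1 differed by 3.12, Suclg1 by 3.09, Hist3h2ba by 2.22, Cst3 by 1.47, Eif3e by 1.19, mt-Co1 by 1.16 and Psmb6 by 1.06, each from below 0 in uninjured to above 0 in injured ganglia. Map3k12 differed by -2.38, from 1.35 to -1.03. Xdh differed by -2.05, Dusp1 by -1.95 and Car3 by -1.40, each from above 0 to below 0. Without replicate 1 of the uninjured IP the difference of Map3k12 was -1.98. These signs rest on TMM scaling. Library totals moved the median of all genes by -0.58 in both states. That shift is larger than the injured ratios of Eif3e (0.32) and mt-Co1 (0.56) and the uninjured ratio of Dusp1 (0.54), so their change of sign depends on the scaling.

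The IP held high levels of mRNAs of small proteins and low levels of those of very large proteins in both states. Genes of small proteins outside the ribosome, respiratory chain and proteasome had a median log2 ratio to input of 2.17 in uninjured and 2.82 in injured ganglia, and genes of very large proteins -1.49 and -1.60, so a trend with transcript length, which was not measured, or a difference in library preparation between IP and input may account for much of the pattern. The ribosomal protein median minus that of the other small-protein genes was -0.34 (bootstrap interval over genes -1.04 to 0.36) in uninjured and -0.20 (-0.86 to 0.66) in injured ganglia. An association of ribosomal protein mRNAs with CSDE1 beyond that of the other small-protein genes stays open, as both intervals span 0. A control precipitate was not analysed here, and binding to CSDE1 as such was not tested.

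Ribosomal protein and oxidative phosphorylation mRNAs were more enriched in the injured IP than in the uninjured IP. A lower input after injury is argued against, as the ribosomal protein input median rose by 0.22 (0.17 to 0.26) and that of oxidative phosphorylation changed by -0.10 (-0.15 to -0.05), against differences of 0.77 and 0.62. Scaling or a few abundant genes would move all genes alike, whereas the ribosomal protein median lay 0.76 (0.64 to 0.89) above that of all genes. The bracketed intervals here come from a bootstrap over genes and hold no spread between samples. Other small-protein genes differed by 0.59, against -0.15 to 0.24 for matched random lists, so a different recovery of small-protein mRNAs in these 2 IP samples may account for the pattern. An effect of injury on CSDE1 binding stays open and untested, since each state has 1 IP sample.

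The 3 IP columns of a state differed far less than the inputs did. The chi-square per degree of freedom over high-count genes was 0.96 in uninjured IP (81 genes). This lies within the 95% range of 0.794 to 1.23 for pure sampling of these genes, as a single set of reads divided into 3 columns may give. In injured IP it was 1.13 (237 genes, chi-square p = 0.0264), slightly above pure sampling. Separate libraries that varied as the inputs of the same state did over high-count genes would give 3.17 (lower bound 2.52) and 6.32 (lower bound 5.54), above the values seen. These bounds treat genes alike, although abundant ones such as Bc1, at 7.74% of uninjured IP counts, weigh more, so the true range is wider. Over genes with at least 20 counts the median extra variation was 0 in the uninjured inputs and both IP groups, and 2.41% in the injured inputs. Over all genes with at least 20 counts the values of 1.17 and 1.18 left a small excess over pure sampling (chi-square p = 1.8e-40 and 2.3e-54). Its source was not tested. No biological explanation was tested.

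Of the 10 splits of the 6 input libraries into groups of 3, 1, the real split, gave as many genes (4778, fitted on the inputs alone), and the highest of the others gave 0. With 10 splits a share under 0.05 cannot be reached.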

How the results depend on the processing

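The 12 columns taken as separate samples and the single ratio per state were added after the data were seen. The length and GC corrections, with or without the block, were not run for want of transcript lengths and GC content on the build used. Also not run were the replicate block in comparisons with IP, where the columns of a state are 1 sample, the compared groups alone for the difference in enrichment and for IP against IP, and a fold threshold where there is no test. The replicate block could be fitted for the input comparison, where it called 2441 higher and 2394 lower genes, and of 31 lists it left 30 calls as they were and added 1. Correlations of same-numbered inputs, centred on their group means, were 0.0223, 0.0304 and 0.000479 over all tested genes. Over genes with a mean of at least 100 input counts they were -0.0344, 0.101 and 0.0590. No clear pairing by number was seen, and with 3 libraries per group a pairing could not be excluded.

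Counts of called genes stayed within 1.5 times of the given ones under all alternatives run, except that for injured against uninjured input DESeq2 called 1164 higher and 1270 lower and the fold threshold of 1.5 called 565 and 288, the latter by its own construction. The Csde1 ratio of IP to input reversed with library totals, to -0.20 in uninjured and -0.15 in injured ganglia, by about the shift of the median of all genes (-0.58 in both states). Limma on 1 ratio per state gives 1 mean over both states, which for Car3 was 0.18 (adjusted p = 0.675), between its uninjured and injured values of 0.92 and -0.48. Csde1, at 0.38 and 0.43, also lost its call with limma-voom (0.39 and 0.44, adjusted p = 0.147 and 0.0783), a fold threshold (same values, adjusted p = 0.893 and 0.808) and limma on 1 ratio per state (0.41 for both states, adjusted p = 0.116), so the spread or the threshold ended these calls and not the size of the ratio. Of the genes named for the inputs, 4 lost their call with limma-voom, among them Acta1 (2.68, adjusted p = 0.0986, against 2.84) and Plp1 (0.36, adjusted p = 0.0541, against 0.37), 4 with DESeq2 and 27 with the fold threshold. In injured ganglia Car3 lost its call with DESeq2, limma-voom, RLE, the stricter filter, the compared groups alone and the fold threshold (adjusted p = 0.0557 to 0.595). The correlation of enrichment between states, 0.919, was 0.923 with library totals, 0.946 with the stricter filter and 0.942 over 12 columns, and 0.898 to 0.917 with a column left out. An IP column left out removes part of the counts of 1 sample, so ranges from left-out IP columns hold no spread between precipitates. Leaving out a column gave 5726 to 6153 higher and 4588 to 4954 lower genes in uninjured IP against input, 6291 to 6643 and 5237 to 5547 in injured, 1742 to 2340 and 1781 to 2358 for the inputs, 419 to 514 and 166 to 225 for the difference in enrichment, and 1077 to 1189 and 427 to 490 for IP against IP. With 12 columns as first designed, which treats the IP columns as replicates, tests called 1513 and 1288 genes for the difference in enrichment and 3099 and 2734 for IP against IP. None of the list calls held with an estimated correlation (0 of 10, 9 and 19), and with fry the input calls of oxidative phosphorylation (adjusted p = 0.108) and myelinating Schwann cells (0.113) were lost. Fry, which tests a list against no change and not against other genes, also passed 12 further lists for uninjured IP against input, 11 for injured and 4 for the inputs, among them mRNAs named as CSDE1 targets (adjusted p = 0.00081, 0.00084 and 0.0157, against 0.509, 0.457 and 0.139 with camera).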

Other observations

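The values of single genes in this part were chosen after they were seen. The mRNAs of the mitochondrial genome differed widely in their ratio of IP to input in uninjured ganglia. mt-Nd5 and mt-Co1 went from 225 to 136 CPM and from 1895 to 1245 CPM, while in injured ganglia mt-Nd5 fell from 248 to 132 and mt-Co1 rose from 2064 to 3038 CPM (log2 0.56). mt-Cytb went from 434 to 731 CPM (log2 0.75), mt-Nd1 from 164 to 1330 (3.02), mt-Nd4 from 89.2 to 691 (2.95) and mt-Nd2 from 29.8 to 330 (3.47). mt-Co2, mt-Co3 and mt-Atp6 were nearly absent from the input, at 0.467, 0.544 and 0.233 CPM, and stood at 2518, 2461 and 2444 CPM in the IP. The mitochondrial ribosomal RNA mt-Rnr1 went from 2.49 to 1539 CPM and mt-Rnr2 from 660 to 5533. The mitochondrial transfer RNAs mt-Tq and mt-Ts1 had no input count and stood at 2259 and 2225 CPM in the uninjured IP.

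Some RNAs were seen on one side only. With no count in the 6 inputs, 189 genes had at least 300 counts over the 2 IP samples, 124 of them without a symbol. With no count in the IP samples, 6 genes had at least 300 counts over the inputs. Alpha enolase, summed over Eno1 and its copy Eno1b, lay at log2 -2.41 in uninjured and -2.84 in injured IP against input, opposite to most oxidative phosphorylation mRNAs.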
